A study of Mus musculus with 4 samples.

How the data were processed

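Gene tables from mouse endometrium were analysed, 1 for each of 4 libraries, with an Ensembl gene identifier, a symbol, a count and an FPKM value, for 28545 genes in each. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit; the labels do not say whether counting used strand. The submitters' processing notes name HISAT2, HTSeq 0.13.5 and the build GRCm38. Per the file headers, the authors deposited whole-number read counts per gene, not normalized, and FPKM beside them. The deposited FPKM values equal the count divided by gene length and by the library's total count: lengths worked out from 2 or more libraries were the same within 1e-06 for 23463 of 23463 genes. These lengths matched the merged exon length in GENCODE mouse release 21 within 0.1 percent for 22159 of 22537 genes (98.3%), and 28472 of 28545 identifiers were found in it. Coordinates and exon overlaps are from that annotation on GRCm38. Across the files 1166 genes had no count in any library. FPKM per total count makes each library's values relative to its own RNA, and HTSeq in its default mode leaves out reads that cannot be assigned to 1 gene, so genes with overlaps or close copies can be undercounted; its settings are not given in the sources used here.

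Before the data were examined, the design was fixed for tables of FPKM alone, as limma on log2(FPKM + 1). The files hold counts as well, so the main test was the one that counts need: edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) with TMM scaling, the group as the only term and 2 residual degrees of freedom. Genes with a mean FPKM of at least 1 were tested, which left 13513 and set 15032 aside. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested. SE is the log2 fold change divided by the square root of the test statistic. CPM uses TMM-scaled library sizes. Total counts per library ran from 17444368 to 22950532, and a floor of 3 counts corresponds to 0.127 to 0.173 CPM.

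Gene lists for pathways and cell types were fixed before the data were examined, 38 in all, and the 35 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Of these, 16 were called, 4 higher and 12 lower, and 0 with an estimated correlation (lowest adjusted p = 0.241). Named genes were Smad7 and the 12 genes in each direction with the largest change among those that passed. The 4 members of each list with the smallest p were named, as were genes chosen beforehand for the subject of the series title. Since no gene passed, the 12 with the smallest unadjusted p whose groups did not overlap were taken. Predicted and unnamed genes were left out. Other members and genes named beyond these rules were chosen after their values were seen: Id4, Sprr2e, Sprr2f and Foxl2 in the report, and in the closing section Myh11, Gm42031, Atp13a5 and clock genes other than Per2. For genes with few counts, ratios carry 95% exact binomial intervals.

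The procedure was tested on simulated data for the comparison of 2 against 2 libraries over 13513 genes, with the real means, library sizes and a spread of 0.401 and 0.163 in the groups. edgeR recovered 39% of 100 genes changed 4-fold and 96% of 100 changed 16-fold, with 1 false call among 13293 unchanged genes. DESeq2 1.42.0 recovered 83% and 96%, with 25 false calls. A list of 20 genes shifted 2-fold was called, and 0 of 35 unshifted lists. Genes were simulated independently, so this could not show how list calls fare among correlated genes. All genes of a group were given the same spread, so the recovered shares need not hold for real genes, whose spread differs. In the real data Serpina9, with a fold change of 78.6, had an edgeR adjusted p of 0.0919. Estimated correlations in the real lists ran from -0.15 for neutrophil genes to 0.99 for proliferation genes. Alternatives were the filter, scaling, pseudocount, limma settings, the replicate number as a block, each library left out, other list tests and, added after the data were seen, DESeq2, scaling by total counts and 2 other quasi-likelihood fits. The planned limma test on log2(FPKM + 1) was kept as an alternative.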

Results

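Polyadenylated RNA from mouse endometrium, the inner layer of the uterus, was sequenced in 4 libraries. The design text of the series gives 1 stage for all the mice, proestrus, the phase of the cycle that precedes ovulation, and it speaks of uterine tissue where the sample labels name endometrium. The labels describe 2 libraries from mice whose Smad7 gene carries loxP sites (labelled floxed) and 2 from such mice that also carry Cre recombinase (labelled Cre). Cre removes DNA between loxP sites, so the comparison asks how the tissue differs when Smad7 is deleted; the series title names a change of stromal cells towards myofibroblasts and autophagy. The Cre line and the deleted exons are not given in the sources used here. Total counts per library were 22950532 and 18193504 in the libraries labelled floxed, and 19830568 and 17444368 in those labelled Cre. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these libraries, which may be technical.

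Smad7, which encodes an inhibitor of TGF-beta and BMP receptor signalling, was read first because it checks the labels. It was higher, not lower, in the libraries labelled Cre. The 2 libraries labelled floxed held 34.3 and 36.8 CPM (counts scaled to library size), and the 2 labelled Cre held 227.6 and 154.0 CPM. The deposited FPKM values averaged 7.80 ± 0.0127 in the first group and 41.9 ± 11.3 in the second (SD, n = 2 each), from 808, 642, 4473 and 2674 counts. The log2 fold change was 2.42 ± 0.28 (SE), with an adjusted p of 0.0982 in edgeR's quasi-likelihood test, which did not pass 0.05. It passed in 4 of 20 settings. These were without floxed replicate 1 (2.37) and without floxed replicate 2 (2.47), when the spread came from the Cre pair alone, with DESeq2 (2.43, adjusted p 8.5e-11) and with no filter on low genes (2.37). It did not pass without Cre replicate 1 (2.11) or without Cre replicate 2 (2.68). An exact two-sided permutation test of the 4 values gave p = 0.333, the smallest that 2 against 2 libraries allow. Smad7 (ENSMUSG00000025880) lies on chromosome 18 from 75367529 to 75395935 on the plus strand of GRCm38, and 0.0% of its exon bases are shared with exons of another annotated gene. Counts were given per gene and not per exon, so loss of a single exon was not analysed here. Since Smad7 goes against the labels, every direction given here is that of the libraries labelled Cre relative to those labelled floxed, and not of a verified loss of Smad7.

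**Figure D1:**
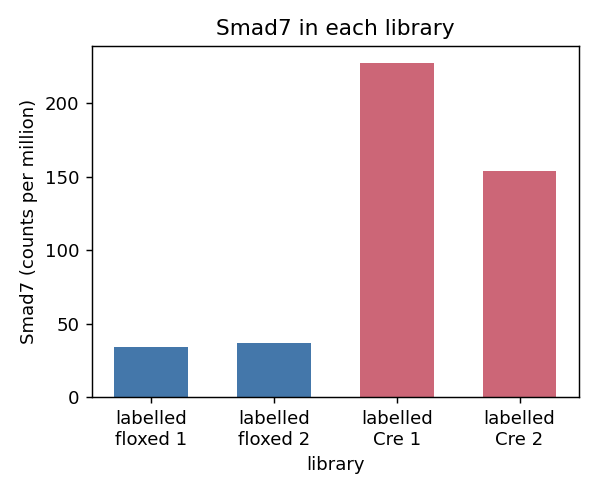
Bars show Smad7 in CPM for each of the 4 libraries, in blue for those labelled floxed and in red for those labelled Cre. The libraries labelled Cre reached 227.6 and 154.0 and the libraries labelled floxed 34.3 and 36.8.

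Lists of interferon response, neutrophil, T and NK cell, macrophage, antigen presentation and cytokine genes had lower values in the libraries labelled Cre than in those labelled floxed, and lists of smooth muscle, mesothelium, and oviduct and ovary genes had higher values. These list calls come from camera with a preset correlation of 0.01, and none passed with an estimated one (lowest adjusted p = 0.241). The estimate was below 0.01 for neutrophil (-0.15), T and NK cell (-0.050), cytokine (-0.040), and oviduct and ovary genes (-0.028). Correlation between genes thus does not account for the loss of those calls, and what else differs between the 2 forms of the test was not examined. No single gene passed the test: of 13513 genes, edgeR called 0 higher and 0 lower at an adjusted p under 0.05, the lowest being 0.0838. At an adjusted p under 0.1 it called 38 higher and 40 lower, and at an unadjusted p under 0.05 there were 987 higher and 889 lower, where 675.65 in all would be expected by chance. The calls at an adjusted p under 0.1 numbered 0 and 0 with total count scaling and without either Cre library, 26 and 29 with median-of-ratios scaling, 16 and 15 with a robust fit, 5 and 6 with the replicate block, and 79 and 75 with limma on log2(FPKM + 1). Of the genes at an unadjusted p under 0.05, 52.6% were higher in edgeR, 54.4% in that limma test and 71.3% in limma on TPM. DESeq2 called 438 higher and 405 lower on the same counts. In 48.3% of the genes the groups did not overlap, where chance gives 33.3% if all 4 libraries vary alike. They did not, so 33.3% is not an exact reference here. The spread was uneven, with a biological coefficient of variation of 0.401 between the libraries labelled floxed and 0.163 between those labelled Cre. The libraries labelled floxed were about as unlike each other as libraries of different groups, for which it was 0.389 to 0.423. Spearman correlations were 0.908 for the floxed pair, 0.912 to 0.920 between groups and 0.985 for the Cre pair. By Pearson correlation the floxed pair had 0.9084, and pairs between groups at most 0.9075. Without floxed replicate 1 edgeR called 2364 genes higher and 1885 lower, and without floxed replicate 2 it called 1401 and 1541, each time with the lone floxed library assumed to vary like the Cre pair. Without Cre replicate 1 or Cre replicate 2 it called 0, with 658 and 618 genes at an unadjusted p under 0.05.

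The 12 genes with the smallest p among those higher in the libraries labelled Cre had adjusted p-values of 0.0919 and did not pass. Each passed in 4 of the 19 or 20 settings: with DESeq2, with no filter and with either floxed library left out. None passed in the others, which include either Cre library left out. Per2, a repressor of the circadian clock, averaged 129 ± 12.2 CPM in the libraries labelled Cre and 19.2 ± 1.24 in those labelled floxed (SD, n = 2 each), a log2 fold change of 2.74 ± 0.22 (SE). Lgr6, a receptor for R-spondins, averaged 53.2 ± 4.73 against 2.89 ± 0.842 CPM. Dpp6, an auxiliary subunit of potassium channels, averaged 64.9 ± 1.15 against 8.43 ± 0.322 CPM, and Kcne4, another such subunit, 128 ± 7.02 against 27.9 ± 0.171 CPM. Serpina9 stood at 42.7 and 28.5 CPM in the libraries labelled Cre and at 0.680 and 0.172 in those labelled floxed. It had 19 counts in the libraries labelled floxed together and 1333 in those labelled Cre. The ratio of floxed to Cre was 0.0129, and 0.0048 to 0.0189 with 1 library left out. The others were Flrt1, Tnfaip8l3, Slitrk3, Scml4, Ppp1r1b, Mfsd4a and Fam83e, with log2 fold changes from 2.19 for Scml4 to 4.80 for Fam83e. Exons of Mfsd4a and Ppp1r1b overlap those of other genes over 23.9% and 15.7% of their length, so reads there were uncertain.

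None of the 12 lower genes passed (adjusted p 0.0919 for each). Each passed in the same 4 of 19 or 20 settings, with DESeq2, with no filter and with either floxed library left out, and in no other. Cldn4, a tight junction protein of epithelium, stood at 16.2 and 15.9 CPM in the libraries labelled Cre and averaged 74.8 ± 0.227 in those labelled floxed, a log2 fold change of -2.22 ± 0.19 (SE). Mmp11, a matrix metalloproteinase, averaged 27.8 ± 2.27 against 148 ± 26.1 CPM, with 5.58% of its exon bases shared with another gene. The interferon-induced genes Ifit1, Ifit3 and Ifit3b had log2 fold changes of -2.38, -2.75 and -2.45, and reads of Ifit3 and Ifit3b, which are close copies, may be shared. The immunoglobulin variable segments Ighv1-74, Igkv6-23 and Igkv10-96, also members of a family of like sequences, had -5.34, -2.16 and -2.22. Several lower genes were nearly absent from the libraries labelled Cre. Acod1, which makes itaconate, had 2559 counts in the libraries labelled floxed together and 7 in those labelled Cre, a ratio of 330.2 with a 95% exact counting interval from 160.0 to 822.1; the libraries labelled floxed held 82.1 and 35.9 CPM, and leaving out 1 library at a time gave ratios from 189.7 to 1084. Cxcr2, a chemokine receptor of neutrophils, had 267 and 3 counts, a ratio of 80.4 (27.2 to 392.3), and 64.0 to 113.1 with 1 library left out. S100a8, a calcium-binding protein of neutrophils, had 714 and 4 counts, a ratio of 161.2 (62.7 to 593.3), from 11.3 and 25.7 CPM in the libraries labelled floxed, and 100.8 to 342.4 with 1 library left out. Sprr2b, a small proline-rich protein of uterine epithelium with close paralogs, had 2005 and 6 counts, a ratio of 301.8 (138.4 to 823.4), from 25.3 and 80.8 CPM, and 156.2 to 498.2 with 1 library left out. These intervals cover counting error only.

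**Figure D2:**
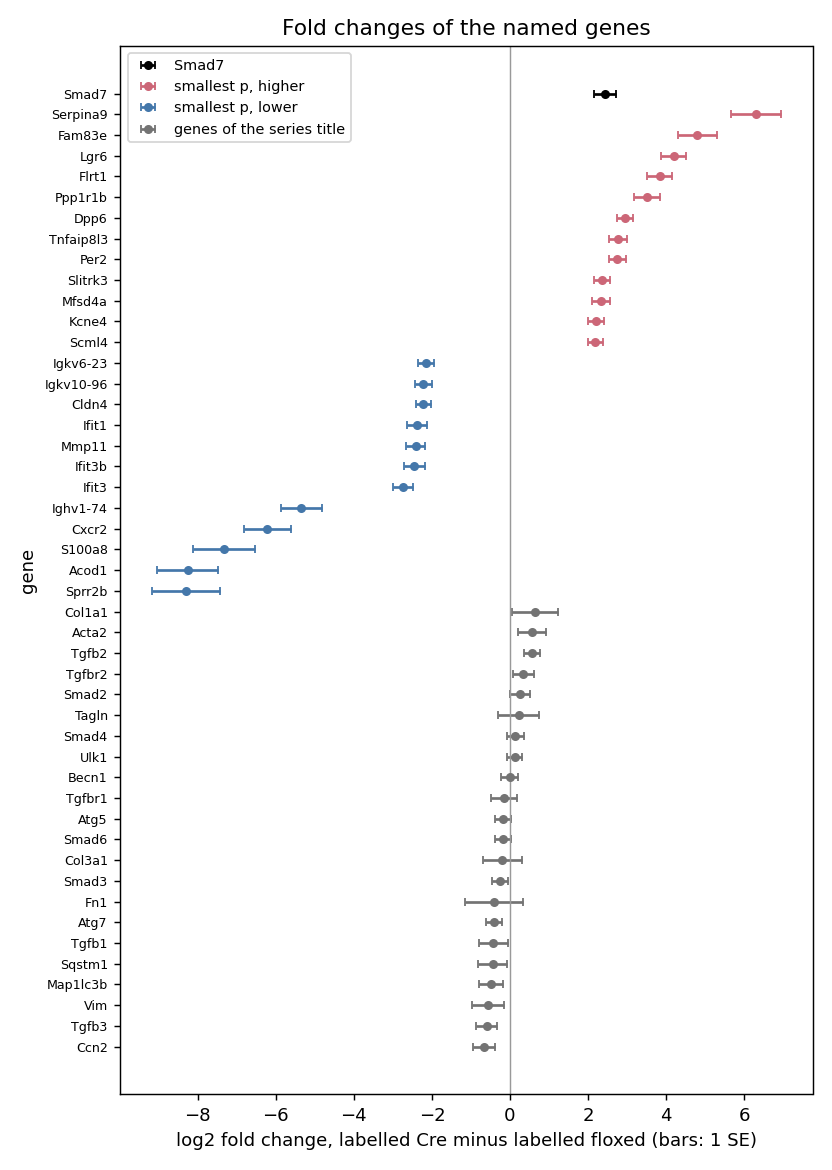
Points are log2 fold changes, labelled Cre minus labelled floxed, and bars are 1 SE from edgeR. Shown are Smad7, the 12 genes with the smallest p in each direction, and genes chosen beforehand for the subject of the series title. Smad7 lies at 2.42, Serpina9 at 6.30 and Sprr2b at -8.30. The genes chosen for the title lie between -0.66 for Ccn2 and 0.64 for Col1a1.

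None of the genes chosen beforehand for the subject of the series title passed the test. Acta2, the smooth muscle actin used as a myofibroblast marker, averaged 3195 ± 11.1 CPM in the libraries labelled Cre and 2162 ± 112 in those labelled floxed (log2 fold change 0.56 ± 0.36, adjusted p 0.53). Smooth muscle expresses Acta2 too, and the smooth muscle list was higher in the same libraries. Col1a1 had a log2 fold change of 0.64, Col3a1 of -0.19, Fn1 of -0.41, Vim of -0.56 and Ccn2, which shares 23.2% of its exon bases with another gene, of -0.66. Fn1 stood at 1589 and 324 CPM in the libraries labelled floxed and at 702 and 739 in those labelled Cre. In the same order, Col3a1 stood at 4125 and 1951 against 3089 and 2229, and Col1a1 at 2884 and 1038 against 3597.5 and 2494. Vim stood at 745 and 1389 against 697 and 748. The directions of Fn1 and Col3a1 thus depended on which floxed library was compared. Tagln counts were low, at 3.27 to 7.33 CPM, and 67.9% of its exon bases overlap other genes, so its level was uncertain. The 18 tested myofibroblast markers had a median log2 fold change of -0.39 (camera adjusted p 0.553), with Fap at 1.04 and Thy1 at -1.61, and 42 matrix genes a median of -0.11 (adjusted p 0.417), where the mean was -0.02 and the direction of camera upward. These lists turned on single floxed libraries: the matrix median was 0.79 without floxed replicate 1 (camera adjusted p 5.7e-08) -0.29 without floxed replicate 2 (0.000427), -0.20 without Cre replicate 1 and 0.12 without Cre replicate 2, and the myofibroblast median was 0.27 (0.222) and -0.51 (0.00328).

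For autophagy, 49 tested genes had a median log2 fold change of -0.065 (camera adjusted p 0.749), with 2 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Pik3c3, the lipid kinase of autophagosome nucleation, averaged 109 ± 9.82 CPM in the libraries labelled Cre and 45.2 ± 7.88 in those labelled floxed, and Optn, an autophagy receptor, 7.16 ± 0.551 against 16.4 ± 6.56 CPM. Becn1 had a log2 fold change of -0.0087, Ulk1 of 0.12, Atg5 of -0.17, Atg7 of -0.41, Sqstm1 of -0.44 and Map1lc3b of -0.48. Exons of Becn1 and Sqstm1 overlap those of Cntd1 and Mrnip over 43.9% and 17.3% of their length, so their levels were uncertain. The autophagy median was -0.19 (0.144) without floxed replicate 1, 0.046 (0.564) without floxed replicate 2 and 0.13 with limma on TPM, and without floxed replicate 2 Sqstm1 was at 0.068. Lysosomal genes had a median of -0.20 (camera adjusted p 0.0522), were called lower in 6 of 16 other settings, among them limma on log2(FPKM + 1) (0.0244), and had -0.12 (0.135) without floxed replicate 1; genes of the mTOR and AMPK pathways had 0.19 (0.14).

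In the TGF-beta and BMP pathways, 11 BMP target genes were lower as a list in the libraries labelled Cre (median log2 fold change -0.90, camera adjusted p 0.000644), a call lost with an estimated correlation between genes (adjusted p = 0.591). Of them 5 were lower at an unadjusted p under 0.05, all 5 also adjusted over the list alone, and 1, Id4, was higher. Id1, an inhibitor of differentiation, averaged 33.9 ± 2.38 CPM in the libraries labelled Cre and 89.4 ± 3.55 in those labelled floxed, and the homeobox genes Msx1 and Msx2, which act in uterine epithelium and stroma, averaged 146 ± 26.4 against 330 ± 10.5 and 21.5 ± 0.138 against 44.1 ± 4.29 CPM. Without floxed replicate 1 the median was -0.41 (camera adjusted p 0.0362). The 26 TGF-beta targets had a median of 0.28 (0.711), with Tgfbi at -1.58 and Snai2 at 1.26, and 35 pathway components 0.19 (0.17), among them Ltbp4 at 1.72, Tgfbr3 at 1.39 and Bmp7 at -1.42. Smad2, Smad3, Smad4 and Smad6 had log2 fold changes of 0.25, -0.25, 0.13 and -0.18, the ligands Tgfb1, Tgfb2 and Tgfb3 (12.4% of whose exon bases overlap other genes) of -0.42, 0.56 and -0.59, and the receptors Tgfbr1 and Tgfbr2 of -0.16 and 0.34. Without floxed replicate 1 the median of the targets was 0.10 and that of the components 0.31, without floxed replicate 2 they were 0.074 and 0.054, and the components had 0.094 without Cre replicate 2 and were called higher only with a filter of 5 (0.28, 0.0459). Tgfb1 was at 0.16 without floxed replicate 1.

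Interferon-induced genes were lower in the libraries labelled Cre (22 tested, median log2 fold change -1.68, camera adjusted p 1.1e-27). Of these 20 were lower at an unadjusted p under 0.05, and 20 adjusted over the list alone, against 0 over all genes. Rsad2, an antiviral protein, averaged 9.06 ± 0.298 CPM in the libraries labelled Cre and 59.5 ± 17.8 in those labelled floxed, and Usp18, a protease that removes ISG15, stood at 11.7 and 12.3 against 42.9 and 35.7 CPM. The call was lost with an estimated correlation between genes (adjusted p = 0.582).

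Neutrophil, T and NK cell, cytokine, antigen presentation and macrophage lists were lower in the libraries labelled Cre as well, while B and plasma cell and eosinophil and mast cell lists were not called. The 7 tested neutrophil genes had a median of -2.13 (camera adjusted p 1.8e-14), and Csf3r, the receptor of G-CSF, averaged 4.14 ± 0.401 against 17.7 ± 6.28 CPM. The 13 T and NK cell genes had a median of -1.80 (1.9e-12), with Gzmb, a granzyme, at 4.45 ± 0.756 against 23.2 ± 2.64 CPM and Prf1, perforin, at 1.77 ± 0.346 against 10.6 ± 0.265 CPM. The 19 cytokine genes had a median of -2.17 (2.5e-08), and 10 of them were lower adjusted over the list alone. The 4 of smallest p were Il1b at -4.78, Ccl5 at -2.12, Tnf at -3.20 and Ptgs2 at -3.69. Ptgs2 stood at 1.27 and 2.42 CPM in the libraries labelled Cre and, unevenly, at 36.1 and 11.35 in those labelled floxed. Antigen presentation genes had a median of -0.89 (0.000375) and -0.52 without floxed replicate 1 (0.0345), and macrophage genes -0.98 (0.000636), though -0.47 (0.302) without floxed replicate 1; Cd163 went the other way at 1.25. With an estimated correlation adjusted p-values were 0.241 for neutrophils, 0.241 for T and NK cells, 0.241 for cytokines, 0.591 for antigen presentation and 0.828 for macrophages. The fry test, which asks whether a list moves one way, gave an adjusted p of 0.0275 for neutrophils and 0.0275 for T and NK cells. B and plasma cell genes had a median of -0.73 (camera adjusted p 0.0564), were called lower in 4 of 15 other settings, among them without floxed replicate 1 (-0.94, 0.0406), and had -0.48 without floxed replicate 2 and -0.26 without Cre replicate 2. Eosinophil and mast cell genes had 0.57, with 6 of 8 members higher and a mean of 0.11 (0.377), and 0.98 without floxed replicate 2.

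Lists of neighbouring tissues were higher in the libraries labelled Cre. The 20 smooth muscle genes had a median of 0.72 (camera adjusted p 3.2e-06), with 8 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone, and Smtn, smoothelin, averaged 388 ± 55.8 against 187 ± 25.7 CPM, with 16.3% of its exon bases shared with other genes. The 6 mesothelium genes had a median of 1.49 (0.000277), with Upk3b at 1.50 the member of smallest p and Bnc1 at 2.18. Bnc1 was low and uneven, at 11.5 and 5.82 CPM in the libraries labelled Cre and 2.85 and 0.917 in those labelled floxed. Of 14 oviduct and ovary genes, 7 passed the filter on mean FPKM, Hsd3b1 through the libraries labelled Cre alone. With a filter of 5 too few were left to test. The 7 had a median of 1.81 (6.9e-08). The bound given below for Hsd3b1 lies above that median and so could not move it, and camera was not rerun with the bound. Foxj1, the regulator of motile cilia, stood at 26.3 and 74.9 CPM in the libraries labelled Cre and at 1.53 and 3.67 in those labelled floxed, and Star, the cholesterol carrier of steroid synthesis, averaged 28.0 ± 4.12 against 8.98 ± 0.195 CPM. Foxl2, also high in the libraries labelled floxed, averaged 56.3 ± 13.3 against 55.4 ± 1.05 CPM. Hsd3b1, a steroid dehydrogenase with close paralogs, had 0 counts in both libraries labelled floxed and was at least 25.2-fold higher in those labelled Cre, against a floor of 3 counts per library. Lymphatic genes had a median of 0.71 (0.00854), but 0.49 (0.0864) without floxed replicate 2 and 0.51 (0.0677) without Cre replicate 2. With an estimated correlation adjusted p-values were 0.591 for smooth muscle, mesothelium and lymphatic genes and 0.241 for oviduct and ovary genes.

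Cell cycle genes were highest in 1 library. All 34 tested proliferation genes had a log2 fold change below 0 (median -1.35, camera adjusted p 8.4e-07), and all 34 were higher in floxed replicate 1 than in floxed replicate 2, by a median ratio of 3.97. Without floxed replicate 1 the median was 0.089 (0.839). Mcm7, a helicase subunit of DNA replication, held 110 and 72.3 CPM in the libraries labelled floxed against 32.1 and 35.5 in those labelled Cre, and 12.6% of its exon bases overlap other genes. Progesterone response genes had a median of -0.63 (0.0347) and matrix remodelling genes of -0.33 (0.0452), and without floxed replicate 1 these were 0.35 (0.987) and 0.33 (0.819). Matrix remodelling genes had -0.65 without floxed replicate 2 and a camera adjusted p of 0.207 without Cre replicate 2. The progesterone call was lost in 7 of 16 other settings, among them limma on log2(FPKM + 1) (0.183), and the matrix remodelling call in 9, among them the same limma test (0.114) and the replicate block (0.0662). Ribosomal protein genes had a median of -0.45 (0.0144) and 0.28 (0.0348) without floxed replicate 2, and oxidative phosphorylation genes -0.26 (0.0255) and -0.049 (0.714), with 0.0589 and 0.184 in camera adjusted p without Cre replicate 2 and medians of -0.91 and -0.41 without floxed replicate 1. Both calls were lost with quantile normalization (0.531 and 0.241), and that of oxidative phosphorylation with a filter of 5 (0.0583). With an estimated correlation the adjusted p was 0.828 for each of these 5 lists.

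**Figure D3:**
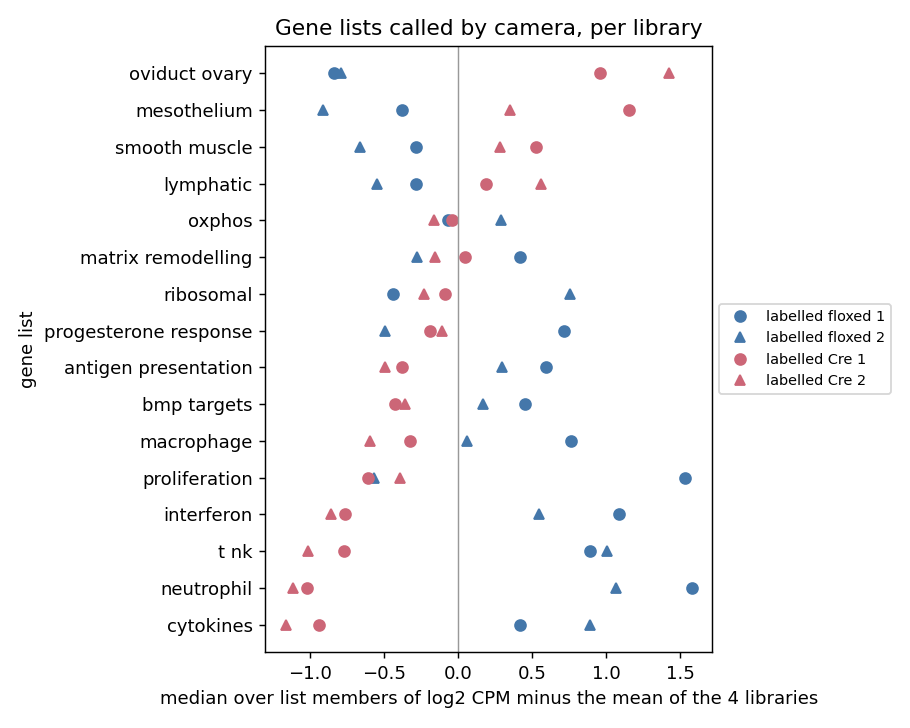
Each point is the median over the members of a gene list of log2 CPM minus the mean of the 4 libraries, for the 16 lists that passed camera with its preset correlation. Neutrophil genes lie at 1.58 and 1.07 in the libraries labelled floxed and at -1.02 and -1.11 in those labelled Cre, and proliferation genes lie at 1.54 in floxed replicate 1 alone.

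The estrogen response list went both ways. Its 18 genes had a median log2 fold change of 0.82 but a mean of -0.07 (camera adjusted p 0.174), with 4 higher and 4 lower adjusted over the list alone. Greb1, an estrogen-induced growth gene, averaged 176 ± 11.2 CPM in the libraries labelled Cre and 25.6 ± 17.6 in those labelled floxed, and Muc4, a mucin, 173 ± 10.7 against 90.4 ± 2.32 CPM (7.68% and 5.33% of their exon bases overlap other genes), while Sprr2b and its paralogs Sprr2d, Sprr2e and Sprr2f were the 4 lower. The list's median was 1.42 (1.8e-08) without floxed replicate 2 and 0.49 (0.977) without floxed replicate 1, and the list was called higher in 7 of 16 other settings, among them limma on log2(FPKM + 1) (1.04, 0.0442). Epithelium genes had a median of -0.068 (0.14), although Cldn4 and Wnt7a were 2 lower adjusted over the list alone, and the median was -0.56 without floxed replicate 1 (0.000414), 0.22 without floxed replicate 2 (0.098), -0.18 and -0.12 without Cre replicate 1 and 2, and -0.12 with no filter, where the list was called (0.0353). Stroma genes had -0.22 (0.313), endothelium -0.26 (0.313), glands -0.16 with camera's direction upward (0.952), pericytes -0.054 (0.952), decidualization -0.16 (0.711), adipocytes 0.17 (0.805), immediate early genes 0.081 (0.388) and mitochondrially encoded genes -0.17 (0.315). Without floxed replicate 2 immediate early genes had 0.20 (0.00175), without Cre replicate 1 adipocytes had 0.65 (0.0235), and without Cre replicate 2 mitochondrially encoded genes had -0.54 (0.0241). Over the libraries left out, medians ran from -0.69 to 0.26 for glands, -0.34 to 0.28 for pericytes, -0.57 to 0.012 for decidualization, -0.53 to 0.74 for adipocytes, -0.54 to 0.084 for mitochondrially encoded genes, -0.0013 to 0.20 for immediate early genes, -0.44 to -0.17 for stroma and -0.31 to -0.13 for endothelium. Lists for nerve, red blood cells and skeletal muscle had fewer than 5 tested members and were not tested.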

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

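DESeq2, total count scaling and 2 other quasi-likelihood fits were added after the data were seen; limma at a pseudocount of 1, the test planned for files without counts, was made an alternative then. Smad7 was higher in the libraries labelled Cre in all 20 settings, with log2 fold changes from 1.85 to 2.68, and passed in 4: 2.37 with no filter, 2.43 with DESeq2, and without either floxed library; leaving out 1 library gave 2.11 to 2.68. Genes called higher and lower were 995 and 933 with no filter, 438 and 405 with DESeq2, and 38 and 40 at an adjusted p under 0.1; 1 and 0 with a filter of 5, with the newer quasi-likelihood fit and with limma on TPM; leaving out 1 library gave 0 to 2364 higher and 0 to 1885 lower. In the other settings both counts were 0. When a floxed library is left out, the spread is read from the Cre pair alone; the cause of the other differences was not tested. In limma at a pseudocount of 1, TPM in place of FPKM moved the median gene to 0.15 from -0.014 and the share higher at an unadjusted p under 0.05 to 71.3% from 54.4%, so directions of small changes are relative to that shift. The replicate block, where numbers share only a number (correlation of deviations -0.061), gave 0 calls, Smad7 2.40 (paired by number) and 15 lists.

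Lists called numbered 16, but 0 with an estimated correlation and 2 with fry, and from 11 to 20 in other settings. The calls of interferon, neutrophil, T and NK cell, cytokine, BMP target, antigen presentation, smooth muscle, mesothelium and oviduct lists held in each setting where they were tested with camera's preset correlation. Of 16 other settings, matrix remodelling was called in 7 and progesterone response in 9, while estrogen response and lysosomal genes, not called in edgeR's test of all libraries, were called in 7 and 6. Camera adjusted p-values under each library left out ran from lowest to highest as follows where a direction reversed: proliferation 3.8e-39 to 0.839, progesterone response 2.1e-06 to 0.987, matrix remodelling 4.3e-05 to 0.819 and ribosomal 6.4e-17 to 0.0589. Gene values numbered 3284 under the alternatives. Of these, 2808 stayed, 445 came to pass and 10 reversed. The other 21 changed sign in genes whose log2 fold change with all libraries was smaller than its SE. Such a change need not be small: Fn1, at -0.41 ± 0.74 (SE), stood at 1589 and 324 CPM in the libraries labelled floxed and at 702 and 739 in those labelled Cre. The log2 fold changes of those 10, none of which passed with all libraries, ran over the libraries left out from -0.84 to 0.16 for Tgfb1, -3.24 to 0.87 for Tnc, -0.99 to 0.28 for Rgs5, -1.27 to 0.021 for Cfd, -0.82 to 0.068 for Sqstm1, -1.50 to 0.079 for Rps29, -1.28 to 0.067 for Rpl38, -1.37 to 0.21 for Rps27, -1.20 to 0.099 for Rpl11 and -0.23 to 1.43 for Car3. Depth limits genes under 3 counts per library.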

Other observations

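The tests of Smad7, of the immune lists and of the clock genes were chosen after the results were seen; other splits of the libraries were planned for counts of calls, and their count at an unadjusted p was added after. Several genes of the circadian clock had different values in the groups, though none passed edgeR's test; they were singled out after their values were seen. Per3 stood at 140.5 and 126.8 CPM in the libraries labelled Cre and at 23.2 and 39.1 in those labelled floxed, Per1 at 90.4 and 79.0 against 37.3 and 45.7, and the clock output gene Tef at 358.5 and 336.8 against 100.8 and 149.3. Arntl, the activator of the Per genes, went the other way, at 5.44 and 6.22 against 18.4 and 15.8 CPM. Dbp and Nr1d1 had log2 fold changes of 0.47 ± 0.62 and -0.11 ± 0.44 (SE), and both differed between the libraries labelled floxed. Dbp stood at 178.0 and 135.6 CPM in the libraries labelled Cre and at 47.9 and 178.9 in those labelled floxed. Nr1d1 stood at 92.6 and 90.8 against 57.2 and 141.4. The activator Clock and Nfil3, a repressor of clock outputs, had log2 fold changes of 0.42 ± 0.43 and 0.098 ± 0.26. Per2 had the lowest adjusted p of these genes, 0.0919.

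Of 155 tested immunoglobulin variable segments, 118 had lower and 37 higher values in the libraries labelled Cre, 69 and 10 of them at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05; reads of these like sequences cannot be assigned with certainty, and edgeR's adjusted p was 0.0919 for the 3 segments named in the report. Gm42031 (ENSMUSG00000110386), a long noncoding RNA gene on chromosome 8 from 85125872 to 85132289 of GRCm38, had 1 and 0 counts in the libraries labelled floxed and 934 and 1166 in those labelled Cre, with the lowest adjusted p of the series, 0.0838. It was singled out after its values were seen. The 17 tested genes that start within 250 kb had log2 fold changes between -0.62 and 0.53. Atp13a5, an ATPase gene, had 0 and 2 counts against 123 and 402.

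Smad7 was higher in the libraries labelled Cre. An exchange of 1 floxed with 1 Cre library would leave a high and a low library in each group, and the tables argue against it: the smallest ratio of a Cre to a floxed library was 4.19, and the largest within a group 1.48. An exchange of the labels of both groups as a whole stays open, since SMAD7 restrains BMP signalling and BMP targets had a median log2 fold change of -0.90 where Smad7 was higher (-0.41 without floxed replicate 1), but p was 0.177 unadjusted with an estimated correlation. Higher TGF-beta signalling, which induces Smad7, may also raise it, but the TGF-beta targets had a median of 0.28 with a 95% bootstrap interval from -0.54 to 0.51, which treats genes as independent, and 0.10 and 0.074 without floxed replicate 1 and 2, and the 2 cannot be told apart. Transcript that is still made from a deleted gene was not tested, as counts are per gene.

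The interferon list and 5 immune lists (neutrophil, T and NK cell, cytokine, macrophage, antigen presentation) were lower in the libraries labelled Cre. A single floxed library as the source is argued against for the neutrophil, T and NK cell, cytokine and interferon lists. Their median closest to 0 with either left out was -1.33. It stays open for the macrophage and antigen presentation lists, since without floxed replicate 1 macrophage genes had -0.47 and antigen presentation genes -0.52. With 1 floxed library left out the spread is that of the Cre pair alone, so these medians say nothing of the spread between floxed libraries. More smooth muscle in the samples labelled Cre, whose smooth muscle list was higher and led in abundance by Myh11 at 2774 and 2264 CPM, would lower epithelial genes as much, but these had a median of -0.068 (95% bootstrap interval -0.35 to 0.13) against -1.95 (-2.31 to -1.64) for the first 4 lists, -0.56 (-0.75 to -0.11) against -1.74 (-2.11 to -1.44) without floxed replicate 1, and 0.22 (0.024 to 0.56) against -1.89 (-2.24 to -1.63) without floxed replicate 2; a set of stroma, epithelium and endothelium genes, tested first and replaced by epithelium alone after its value was seen because smooth muscle tissue holds stroma and vessels too, had -0.22 (-0.40 to -0.0059). These bootstrap intervals treat genes as independent and hold no spread between libraries, so whether they overlap decides little alone. The epithelium list was also mixed, with 8 members higher and 12 lower, among them Krt7 at 1.10, Wnt7a at -1.72 and Cldn4 at -2.22. Mesothelium and oviduct and ovary lists were higher in the same libraries, and what such tissue adds to the epithelium list was not tested. The comparison thus bears on smooth muscle alone and not on a mixture of added tissues. For the macrophage and antigen presentation lists, more smooth muscle cannot be told apart. Their median was -0.91 (-1.09 to -0.63) with all libraries and -1.18 (-1.36 to -0.90) without floxed replicate 2, below that of epithelium. Without floxed replicate 1 it was -0.49 (-0.73 to -0.27), an interval that overlapped that of epithelium. The design text of the series gives proestrus for all the mice, which speaks against a different stage of the estrous cycle, but no measure of stage in each animal was analysed here and the genes leave it open, as the estrogen response list had a camera adjusted p of 0.174 in edgeR's test but was called higher in 7 of 16 other settings, among them limma on log2(FPKM + 1) (0.0442), and had 0.977 without floxed replicate 1; the genotype that the labels name stays open too, untested.

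A candidate explanation for the clock genes is that the groups were collected at different clock times. A signed test with fry on 15 clock genes, leaving out Per2 and Bhlhe41, gave p = 0.0692, where an exact permutation of the 4 libraries cannot go below 0.333. Of these genes 12 lay in the direction of that hypothesis and Nr1d1, Clock and Nfil3 against it, with a signed median log2 fold change of 0.87, and the 11 repressor arm genes alone had an unadjusted camera p of 1.5e-07 with the preset correlation and 0.170 with an estimated one. The list was written after values of several members had been seen, so this test decides little. The labels give no time of collection, and an effect of genotype on the clock cannot be told apart from it.

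The 4 libraries can be split into 2 against 2 in 3 ways, too few for a share under 0.05. The labelled split had 1876 genes at an unadjusted p under 0.05, the highest of the others 157, and 1 split, the labelled one, reached that number; each gave 0 genes at an adjusted p under 0.05 in edgeR.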
